A study of Arabidopsis thaliana with 12 samples.

How the data were processed

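Gene expression was measured in 12 samples of pooled whole seedlings, 1 array each, in 4 groups of 3 by genotype (WT or rb10) and light (5 days dark, or the same followed by 1 h of white light). The deposited values are log2 signals per probe set. The submitters' processing notes name RMA and GCRMA, methods that correct background, normalize arrays and summarise probes, with no version and without saying which gave these values. They were used as deposited. All 38408 probe sets have a value on every array. Array signal gives no count from which a depth could be stated.

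Probe sets were paired with genes through accessions and locus codes in a table of the TAIR10.1 annotation, used for names only, since the deposited files do not state a build. Of the probe sets 16722 were paired with 1 gene, 759 with several and 20927 with none, and the 17481 with at least 1 gene were tested with no filter on signal. Of the genes, 145 had several probe sets, and the one with the highest mean over the 12 arrays stood for the gene. Symbols are those of that table, with older names beside them where the lists used another.

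One linear model with 4 group means was fitted to each probe set over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes, 8 residual degrees of freedom and 2.79 from the prior). The 5 comparisons were light against dark in WT, light against dark in rb10, rb10 against WT in the dark, rb10 against WT after light, and the difference of the light effects. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Figures were drawn with matplotlib 3.10.9.

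Before the data were examined, 25 gene lists with 434 entries were fixed, of which 76 could be paired with a probe set and are called measured. The 13 lists with at least 3 measured members were tested with camera in limma, with a preset correlation of 0.01 between genes and with a correlation estimated from the data, and p-values were adjusted over lists within a comparison. They were genes promoted by PIF factors and shade, chlorophyll synthesis, photosynthesis, flavonoids, seed oil, sugar starvation, autophagy, ribosomal proteins, ribosome biogenesis, cell wall, abscisic acid, stomatal markers and reference genes. A further 8 lists had 1 or 2 measured members (TOR complex, light signalling, clock, starch, cell cycle, oxidative stress, ethylene, root cells) and 4 had none (brassinosteroid and gibberellin synthesis, seed storage, nitrogen, vascular markers). Members were also counted with p-values adjusted over the list alone.

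The genes named were set by a rule fixed at the same time. It took the 5 largest rises and the 5 largest falls among called probe sets with 1 gene whose replicates did not overlap between the groups (without that condition for the interaction), up to 3 called members of each list or else the member with the smallest p, and RAPTOR1B, RAPTOR1A, TOR and the reference genes. Lists of small heat shock proteins, late embryogenesis abundant proteins, root barrier genes and root hair genes, the test of 36 families of gene symbols with at least 8 members, and every repeat of a count without the array labelled rb10 dark replicate 3 as a doubted array were chosen after the data had been seen.

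Alternatives were a replicate block, the groups of a comparison alone, quantile normalization again, equal array medians, leaving out the lowest 25% of probe sets by mean, testing every probe set, a trended and robust prior, a fold of 2 as well as the adjusted p, an ordinary equal-variance test, and leaving out each array in turn. Simulated data had 200 changed genes among 17481 probe sets and the spread of the fit without the array labelled rb10 dark replicate 3. The test was run on these. For changes of 0.5, 1 and 2 in log2 it recovered 9%, 73.1% and 97% for light in WT (7 false calls), 11.9%, 70.1% and 98.5% for genotype after light (4 false calls), and 7.5%, 64.2% and 92.4% for genotype in the dark with 11 arrays (6 false calls). No sample was left out of the comparisons as labelled.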

Results

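RNA from pools of whole seedlings of Arabidopsis thaliana (ecotype Col-0) was measured on 12 Affymetrix Gene 1.0 ST arrays. Wild type (WT) and rb10 seedlings had spent 5 days in darkness on half-strength MS medium that held no sucrose, and were collected at that point or after a further 1 h in white light. This gave 4 groups of 3 arrays, which the labels call biological replicates. The labels give rb10 as a name only. From what is known of the study it is a mutant of RAPTOR1B, the partner protein through which the kinase TOR, a regulator of growth by nutrients, binds its substrates. The deposited values were log2 signals of 38408 probe sets from 1.26 upward, and the median of each array lay between 6.72 and 6.91. The medians differed by genotype, 6.72 to 6.82 on the WT arrays and 6.88 to 6.91 on the rb10 arrays, except rb10 dark replicate 3 (6.78). A gene could be paired with 17481 probe sets (45.5%), and these were tested. Of the protein-coding genes that carry a symbol of their own 16.8% could be paired with a probe set, against 85.8% of those known by a locus code. TOR and most of the well-known light genes could not be paired, so their values, if among the other probe sets, were not read, and a gene is called measured below only where it was paired. Changes are differences in log2 signal with the standard error (SE) of the limma fit and n = 3 arrays per group, p-values are adjusted by Benjamini-Hochberg within each comparison, and the number of arrays limits the precision. The p-values measure the spread between these samples.

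RAPTOR1 (AT3G08850, also called RAPTOR1B), where the position of the probes relative to any insertion is not given, read 11.71 ± 0.11 in WT in the dark and 11.63 ± 0.06 in WT after light (SD, n = 3). It read 10.98 ± 0.14 in rb10 after light (SD, n = 3). The arrays labelled rb10 dark replicates 1 and 2 read 11.06 and 11.08, while the array labelled rb10 dark replicate 3 read 11.60. This was just below the WT dark arrays (11.63 to 11.84) and inside the WT light arrays (11.58 to 11.69). That array also lay with the WT dark arrays over the genes that differed between the genotypes after light. On an axis from those 3355 probe sets, where 0 is the WT dark mean and 1 a shift as large as after light, it lay at 0.02, the WT dark arrays from -0.03 to 0.029 and the other two arrays labelled rb10 dark at 0.503 and 0.528. Its mean correlation across genes was 0.9909 with the WT dark arrays and 0.9796 with the other arrays labelled rb10 dark. All arrays were kept under their labels, and the number of calls in each comparison is also given without that array, a choice made after its values were seen.

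**Figure D1:**
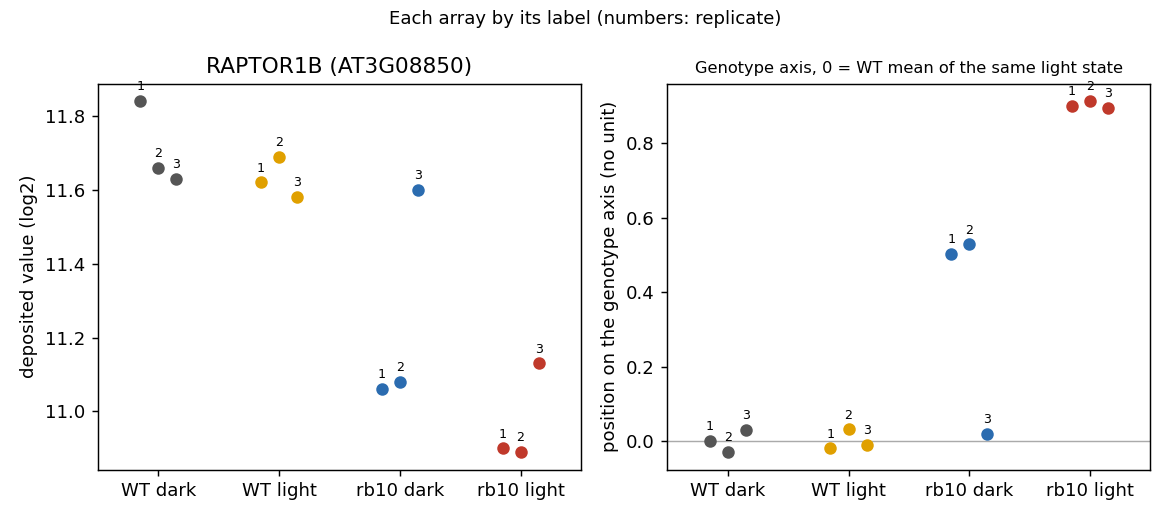
RAPTOR1B signal (left, log2) and position on the genotype axis (right, no unit) of each of the 12 arrays, grouped by label, with the replicate number beside each point. The array labelled rb10 dark replicate 3 reads 11.60 and lies at 0.02, among the arrays labelled WT. Dark and light arrays were placed on separate axes.

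The first comparison asked how 1 h of light changed WT seedlings at the start of greening. The largest rise was that of AT1G54050, a small heat shock protein gene, from 4.0 ± 0.08 to 10.91 ± 0.27 (SD, n = 3), a change of 6.91 (SE 0.27, adjusted p = 3.26e-07). AT1G59860 and AT1G07400, also small heat shock protein genes, rose by 5.66 (SE 0.37) and 5.43 (SE 0.22), AT2G32200 by 5.54 (SE 0.21), and AT5G48570 (ROF2), which encodes a heat-induced prolyl isomerase, by 5.47 (SE 0.33). Among the measured light regulators, HYH, a bZIP transcription factor related to HY5, rose by 2.79 (SE 0.18, adjusted p = 5.42e-06). Both measured genes of the oxidative and singlet oxygen list rose: STZ (ZAT10), a zinc finger protein of stress responses, by 3.15 (SE 0.14) and AT3G28580, an AAA-ATPase gene used as a marker of singlet oxygen, by 2.52 (SE 0.30). GI, a clock component, rose by 0.68 (SE 0.10), and UGT78D2, a flavonoid glucosyltransferase, by 1.60 (SE 0.28).

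The largest falls in WT were those of AT3G53250 (SAUR57, of a family of auxin-induced growth genes), which changed by -2.69 (SE 0.31, adjusted p = 0.000324), AT3G29639 (-2.38, SE 0.40), AT4G10150 (-2.20, SE 0.31), AT3G26445 (-2.12, SE 0.49) and AT4G25260 (-2.12, SE 0.23). Of the 3 measured genes of the list promoted by PIF factors and shade, 2 fell, and 3 fell when adjusted over the list alone. IAA29, an auxin response repressor, changed by -1.67 (SE 0.15) and HAT2, a homeodomain factor, by -0.91 (SE 0.15). As a list they fell against all other genes (median -0.91, camera adjusted p = 0.000742, but adjusted p = 0.128 with an estimated correlation). In the cell wall list (3 measured) EXPA8, an expansin, changed by -1.80 (SE 0.19) and XTH18, a xyloglucan-modifying enzyme, by 1.22 (SE 0.20), and adjusted over the list alone 1 rose and 2 fell. SPCH, which starts the stomatal lineage, changed by -0.93 (SE 0.21), 1 of 3 stomatal markers to pass, with 2 down when adjusted over the list alone. Of the chlorophyll list 1 of 5 (HEMA2, glutamyl-tRNA reductase, 0.47, SE 0.12), 1 of 4 photosynthesis genes (RCA, Rubisco activase, 0.51, SE 0.11) and 1 of 3 flavonoid genes (UGT78D2) rose, and these counts were the same when adjusted over the list alone. EXO, a cell expansion gene induced by brassinosteroids, changed by -0.58 (SE 0.11), 1 of 3 of the sugar starvation list by either adjustment, or 2 without the array labelled rb10 dark replicate 3. None of the 5 seed oil, 14 autophagy, 12 ribosomal protein, 3 ribosome biogenesis and 3 abscisic acid genes passed, nor did any of the 3 reference genes, and adjusted over the list alone 1 abscisic acid gene rose and the other lists gave 0.

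In all, 1204 of 17481 probe sets differed between light and dark in WT (limma), 807 up and 397 down. Without the array labelled rb10 dark replicate 3, which enters only through the shared estimate of spread, 1534 differed, 1196 of the first set among them in the same direction. On simulated data with these groups the same test recovered 73.1% of changes of 1 in log2 and 9% of changes of 0.5 for this comparison. The simulation had 200 changed genes and the spread of the fit without that array (median SE 0.161, against 0.174 with every array). Recovery in the data may therefore differ.

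The second comparison asked the same of rb10. AT3G56290 rose most, by 4.93 (SE 0.28, adjusted p = 6.06e-06), from 5.22 ± 0.30 to 10.15 ± 0.14 (SD, n = 3). AT4G29930, which encodes a basic helix-loop-helix protein, rose by 3.74 (SE 0.29), AT5G48570 by 3.65 (SE 0.33), AT5G12110 by 3.50 (SE 0.24) and AT2G19650 by 3.29 (SE 0.39). HYH rose by 2.90 (SE 0.18), GI by 1.32 (SE 0.10), UGT78D2 by 1.99 (SE 0.28) and RCA by 0.72 (SE 0.11). STZ rose by 1.32 (SE 0.14). Falls were large for AT5G05965 (-3.86, SE 0.34, adjusted p = 6.13e-05), IAA29 (-3.44, SE 0.15), AT3G26445 (-3.07, SE 0.49), AT3G43850 (-2.95, SE 0.32) and AT3G62950 (-2.75, SE 0.46). Their order turned without the array labelled rb10 dark replicate 3, with AT3G26445 at -3.51, IAA29 at -3.38 and AT5G05965 at -3.35. AT3G43850 and AT3G62950 also fell less without it. Their rb10 dark means were then 8.63 and 6.77, against 9.08 and 7.49 with every array.

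All 3 measured genes promoted by PIF factors and shade fell in rb10, by either adjustment: IAA29, FHL (-0.78, SE 0.12), which carries phytochrome A to the nucleus, and HAT2 (-0.75, SE 0.15). The list fell as a set (median -0.78, camera adjusted p = 1.19e-05, and adjusted p = 0.0221 with an estimated correlation). The 3 measured genes of the sugar starvation and amino acid catabolism list also fell together, by either adjustment: ATL8, a RING-type ubiquitin ligase gene (-1.88, SE 0.31), EXO (-1.25, SE 0.11) and MCCB, an enzyme of leucine breakdown (-1.08, SE 0.14). The fall of ATL8 was smaller without the array labelled rb10 dark replicate 3, with an rb10 dark mean of 6.93 against 7.35 with every array. That list too held with either correlation (median -1.25, adjusted p = 1.24e-05, and adjusted p = 0.0221 with an estimated correlation). These were the only 2 of the 13 list calls over the 5 comparisons that held with an estimated correlation. Photosynthesis genes (1 of 4 up, 2 adjusted over the list alone, median 0.46) and flavonoid genes (1 of 3 up, 2 adjusted over the list alone, median 0.44) passed as lists at adjusted p = 0.049, but at adjusted p = 0.302 with an estimated correlation. Autophagy passed at adjusted p = 0.049 (median -0.11, 1 of 14 down, 3 adjusted over the list alone, ATG8E -0.68, SE 0.16), but at adjusted p = 0.569 with an estimated correlation, and at adjusted p = 0.276 without the array labelled rb10 dark replicate 3. In the chlorophyll list 2 of 5 fell, by either adjustment: PORB, a protochlorophyllide reductase (-1.27, SE 0.23), and CHLM, a methyltransferase of chlorophyll synthesis (-0.47, SE 0.12), and the list did not pass (adjusted p = 0.0512). For CHLM the call was lost without the array labelled rb10 dark replicate 3 (-0.37, adjusted p = 0.0958). PPDK, an enzyme that makes phosphoenolpyruvate, changed by -0.88 (SE 0.11), 1 of 5 seed oil genes, or 2 adjusted over the list alone. Among single members of other lists, EXPA8 changed by -0.77 (SE 0.19), FAMA, a guard cell factor, by -1.30 (SE 0.34), and the ribosomal protein gene RPP0A (AT2G40010) by -0.77 (SE 0.16), each the 1 called gene of its list by either adjustment. The calls of EXPA8 (adjusted p = 0.0891) and FAMA (adjusted p = 0.0977) were lost without that array. The 3 stomatal markers had a median of 0.33 but a mean of -0.18 (median -0.21 without that array), and the 3 cell wall genes a median of 0.08 but a mean of -0.17 (median -0.16 without it), with neither list passing. None of the ribosome biogenesis, abscisic acid or reference genes passed by either adjustment.

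In rb10 1254 probe sets differed between light and dark (limma), 598 up and 656 down. Without the array labelled rb10 dark replicate 3 the count was 1108, 922 of them in common and in the same direction. It fell to 782 without the array labelled rb10 light replicate 2, to 580 with the rb10 arrays alone in the fit, and to 137 with an ordinary equal-variance test. Across genes, the light effects in the 2 genotypes were related with Pearson r = 0.452 and Spearman rho = 0.312 (slope of rb10 on WT 0.423, and r = 0.459 without that rb10 dark array), and genes are not independent replicates. Of the called genes 299 rose in both genotypes, where 27.6 would be shared by independent draws, and 142 fell in both, where 14.9 would.

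**Figure D2:**
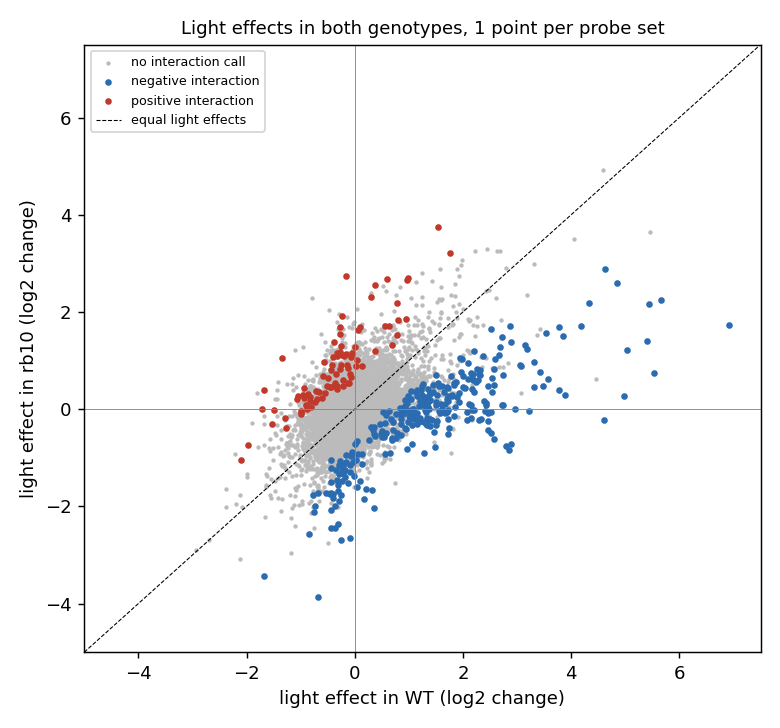
Light effect in WT (horizontal, log2 change) against light effect in rb10 (vertical, log2 change), 1 point per tested probe set, with the dashed line at equal effects. Blue points are the 292 probe sets with a negative genotype by light interaction, and red points the 88 with a positive one.

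The third comparison asked how rb10 differed from WT after 5 days in the dark. With every array under its label, AT3G59130 alone passed, 1.53 higher in rb10 (SE 0.17, adjusted p = 0.0337), a call that was lost with a replicate block (adjusted p = 0.239), with a trended and robust prior (adjusted p = 0.0511), with the dark groups alone in the fit (adjusted p = 0.472) and in most fits that left out 1 array. Leaving out the array labelled rb10 dark replicate 3 left 2 rb10 dark arrays, which are assumed to vary like the other groups. In that fit RAPTOR1 was lower in rb10 by -0.64 (SE 0.11, adjusted p = 0.00775), against -0.46 (SE 0.15, adjusted p = 0.255) with every array. The array was doubted partly for its RAPTOR1 value, so the p-value without it is no independent test of this gene. Without that array, AT4G11190 and AT4G11210, both genes of dirigent-like proteins, were higher by 5.99 (SE 0.37, adjusted p = 2.52e-05) and 4.69 (SE 0.25). AT1G26390, a berberine bridge enzyme-like gene, was higher by 4.72 (SE 0.43), AT1G55990 by 4.21 (SE 0.52), and AT2G23540, a GDSL-type esterase gene, by 4.14 (SE 0.25). Lower in rb10 were AT3G29970 (-4.04, SE 0.26), AT3G17520, a late embryogenesis abundant protein gene (-3.96, SE 0.29), AT1G66000 (-3.82, SE 0.38), AT1G78720 (-3.73, SE 0.14) and AT1G66870 (-3.56, SE 0.28).

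Among the fixed lists in that fit, PORB was higher in rb10 by 0.97 (SE 0.16), 1 of 5 chlorophyll genes by either adjustment (list median -0.11, adjusted p = 0.809). The light-harvesting genes LHB1B2 (-1.09, SE 0.26) and LHCB4.1 (-0.46, SE 0.12) were lower, 2 of 4 photosynthesis genes, with 1 up and 2 down adjusted over the list alone (list adjusted p = 0.443). XTH18 was higher (0.79, SE 0.15), 1 of 3 cell wall genes or 2 adjusted over the list alone, and COR47, a dehydrin gene, lower (-0.42, SE 0.11), 1 of 3 abscisic acid genes by either adjustment, and neither list passed. ICL of the glyoxylate cycle (-0.51, SE 0.10), SDP1, the oil body lipase (-0.40, SE 0.10), and PPDK (-0.40, SE 0.10) were lower, 3 of 5 seed oil genes by either adjustment, and the list did not pass (adjusted p = 0.0696). ATL8 was lower (-1.26, SE 0.20), 1 of 3 of the sugar starvation list by either adjustment (list adjusted p = 0.0847), as were ATG8E (-0.54, SE 0.13) and ATG8B (-0.44, SE 0.12), 2 of the 3 autophagy genes of 14 that passed by either adjustment. With every array, lists passed where no member did: ribosomal proteins were higher (median 0.29, 5 of 12 up and 1 down adjusted over the list alone, adjusted p = 0.000525), as were ribosome biogenesis genes (median 0.30, 1 of 3 up adjusted over the list alone, adjusted p = 0.0429), and autophagy genes were lower (median -0.12, or -0.20 with equal array medians, 0 of 14 adjusted over the list alone, adjusted p = 0.0429). With an estimated correlation these gave adjusted p = 0.443, adjusted p = 0.443 and adjusted p = 0.638. Without the array labelled rb10 dark replicate 3, ribosomal proteins (median 0.36, 3 up and 1 down, 8 up and 1 down adjusted over the list alone) passed at adjusted p = 0.00563, but at adjusted p = 0.364 with an estimated correlation, autophagy at adjusted p = 0.00968, but at adjusted p = 0.306 with an estimated correlation, and ribosome biogenesis did not (adjusted p = 0.0696). With every array the other 10 tested lists had 0 members called and 0 adjusted over the list alone, with no list call.

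With every array 1 probe set was called up and 0 down in the dark (limma), while 2613 had an unadjusted p under 0.05 and an ordinary equal-variance test called 0. Without the array labelled rb10 dark replicate 3, 993 were higher and 768 lower in rb10, 1761 in all.

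The fourth comparison asked how rb10 differed from WT after 1 h of light. The largest differences upward were those of the dirigent-like genes AT4G11190 (6.96, SE 1.32, adjusted p = 0.00494) and AT4G11210 (5.78, SE 0.90), AT4G33610 (4.57, SE 0.85), AT1G55990 (4.57, SE 0.81) and AT5G07475 (4.33, SE 0.82). For AT4G11190 the SE was 0.33 without the array labelled rb10 dark replicate 3, which read 4.48 where the other two rb10 dark arrays read 10.77. The largest differences downward included 3 small heat shock protein genes, AT1G53540 (-5.17, SE 0.31, adjusted p = 1.24e-05), AT1G54050 (-4.57, SE 0.27) and AT1G52560 (-4.56, SE 0.45), with AT2G32200 (-4.44, SE 0.21) and AT5G05965 (-4.29, SE 0.34). RAPTOR1 was lower in rb10 by -0.66 (SE 0.15, adjusted p = 0.0113), while its paralogue RAPTOR2 (AT5G01770, also called RAPTOR1A) differed by -0.01 (SE 0.13, adjusted p = 0.977). AT3G28580 (-3.51, SE 0.30) and STZ (-1.98, SE 0.14) were lower too, both of the 2 measured oxidative stress genes.

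All 3 of the sugar starvation list were lower in rb10 after light by either adjustment, ATL8 by -2.06 (SE 0.31), MCCB by -1.12 (SE 0.14) and EXO by -0.79 (SE 0.11), and the list passed (median -1.12, adjusted p = 0.00177, but adjusted p = 0.08 with an estimated correlation). Of 14 autophagy genes 6 were lower, 7 adjusted over the list alone, ATG8E most (-1.09, SE 0.16), then ATG8B (-0.63, SE 0.14) and ATG8H (-0.41, SE 0.13), which encode the ubiquitin-like proteins of the autophagosome (list median -0.27, adjusted p = 0.00261, but adjusted p = 0.335 with an estimated correlation). Of 5 seed oil genes PPDK (-1.12, SE 0.11), SDP1 (-0.53, SE 0.13) and ICL (-0.51, SE 0.12) were lower by either adjustment, with the list at adjusted p = 0.0589, and at adjusted p = 0.0461 without the array labelled rb10 dark replicate 3 (adjusted p = 0.21 with an estimated correlation). APL3, of starch synthesis, was higher by 1.07 (SE 0.26). The single measured genes EIN3 of ethylene signalling (-0.27, SE 0.10), AUR1 of mitosis (0.27, SE 0.17) and EXPA7 of root hairs (0.41, SE 0.30), and DPE1 of starch breakdown (0.16, SE 0.17), did not pass in any comparison with every array.

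Ribosomal protein genes were higher as a list (median 0.31, or 0.19 with equal array medians, adjusted p = 0.0138, but adjusted p = 0.335 with an estimated correlation). Of 12, RPL7B (AT2G01250, 0.65, SE 0.12) and RPL4D (AT5G02870, 0.42, SE 0.10) were higher and RPP0A lower (-0.82, SE 0.16), with 3 higher and 1 lower adjusted over the list alone. For assembly of ribosomes, BRX1-1 (AT3G15460, 0.89, SE 0.20) and NOP58 (AT5G27120, 0.69, SE 0.17) were higher, 2 of 3 by either adjustment, and the list did not pass (adjusted p = 0.0589). EXPA8 (0.92, SE 0.19) and COB (0.63, SE 0.12), which orients cell expansion, were higher, 2 of 3 cell wall genes, with 2 up and 1 down adjusted over the list alone. SPCH was higher by 1.24 (SE 0.21), 1 of 3 stomatal markers by either adjustment. Of the light-linked lists, IAA29 (-1.52, SE 0.15) and FHL (-0.44, SE 0.12) were lower, 2 of 3 shade genes, with 1 up and 2 down adjusted over the list alone. HEMA2 (-0.67, SE 0.12) and CHLM (-0.42, SE 0.12) were lower, 2 of 5 chlorophyll genes by either adjustment. RCA (0.48, SE 0.11), 1 of 4 photosynthesis genes with 1 up and 1 down adjusted over the list alone, and GI (0.42, SE 0.10) were higher. No flavonoid, abscisic acid or reference gene passed by either adjustment.

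After light 3355 probe sets differed between the genotypes (limma), 1700 higher and 1655 lower in rb10. Setting the array medians equal moved the median of all genes by -0.119 and gave 1231 higher and 2433 lower, so the balance of directions depends on the scaling. The count was 4120 without the array labelled rb10 dark replicate 3 (3339 of the first set in the same direction) and 2141 without the array labelled rb10 light replicate 2. In the fit without that rb10 dark array, 782 probe sets were higher in rb10 both in the dark and after light (117.1 by independent draws). Lower in both were 542 (90.5). The array had been doubted partly over the genes called after light, so its removal itself favours this overlap. The genotype effect averaged over light and the light effect averaged over genotype were related across genes with r = 0.117 and rho = 0.152, and with r = -0.041 without that array.

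The fifth comparison tested whether the light effect differed between genotypes, as the difference rb10 minus WT of the light effects. The heat shock protein genes AT1G54050 (-5.18, SE 0.39, adjusted p = 0.000286), AT1G52560 (-4.84, SE 0.64), AT1G53540 (-4.72, SE 0.44) and ATHSP22.0 (AT4G10250, -4.00, SE 0.52) had a lower light effect in rb10, as did AT2G32200 (-4.79, SE 0.29). AT1G53540, for example, went from 5.61 ± 0.25 to 10.59 ± 0.35 in WT and from 5.16 ± 0.54 to 5.42 ± 0.51 in rb10 (SD, n = 3). The stress genes AT3G28580 (-3.00, SE 0.42) and STZ (-1.83, SE 0.20) also had a lower light effect in rb10. Differences in the other direction were largest for AT1G58460 (2.91, SE 0.35, adjusted p = 0.00272), AT4G17680 (2.40, SE 0.40), AT4G29930 (2.21, SE 0.41), AT4G17670 (2.18, SE 0.29) and AT3G44020 (2.16, SE 0.32). IAA29 fell more in rb10 than in WT (-1.77, SE 0.22), PPDK had a lower light effect in rb10 (-0.83, SE 0.16), and GI rose more (0.64, SE 0.14). MCCB (-0.93, SE 0.19, adjusted p = 0.0338) and SPCH (1.37, SE 0.29, adjusted p = 0.0377) passed with every array, but gave adjusted p = 0.0517 and adjusted p = 0.063 without the array labelled rb10 dark replicate 3. HYH rose by similar values in both genotypes, 2.79 and 2.90. Of the fixed lists only sugar starvation passed (median -0.93, 1 of 3 down, 3 adjusted over the list alone, adjusted p = 0.00112, but adjusted p = 0.0686 with an estimated correlation). Adjusted over the list alone, 1 chlorophyll, 1 seed oil and 1 shade gene were lower, 2 cell wall genes were higher and 1 lower, 1 stomatal gene was higher (median -0.03 but mean 0.42, not passing as a list), and the photosynthesis, flavonoid, autophagy, ribosomal protein, ribosome biogenesis, abscisic acid and reference lists gave 0.

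The interaction passed for 380 probe sets (limma), 292 negative and 88 positive, and for 394 without the array labelled rb10 dark replicate 3, 313 of them in common and in the same direction. Of the 292, 217 had risen in WT, and of these 167 were not called in rb10 and 46 rose there too. The count moved to 208 without WT light replicate 1, 232 without rb10 light replicate 2, 248 without WT dark replicate 2, 250 without WT dark replicate 1 and 250 without WT light replicate 3.

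**Figure D3:**
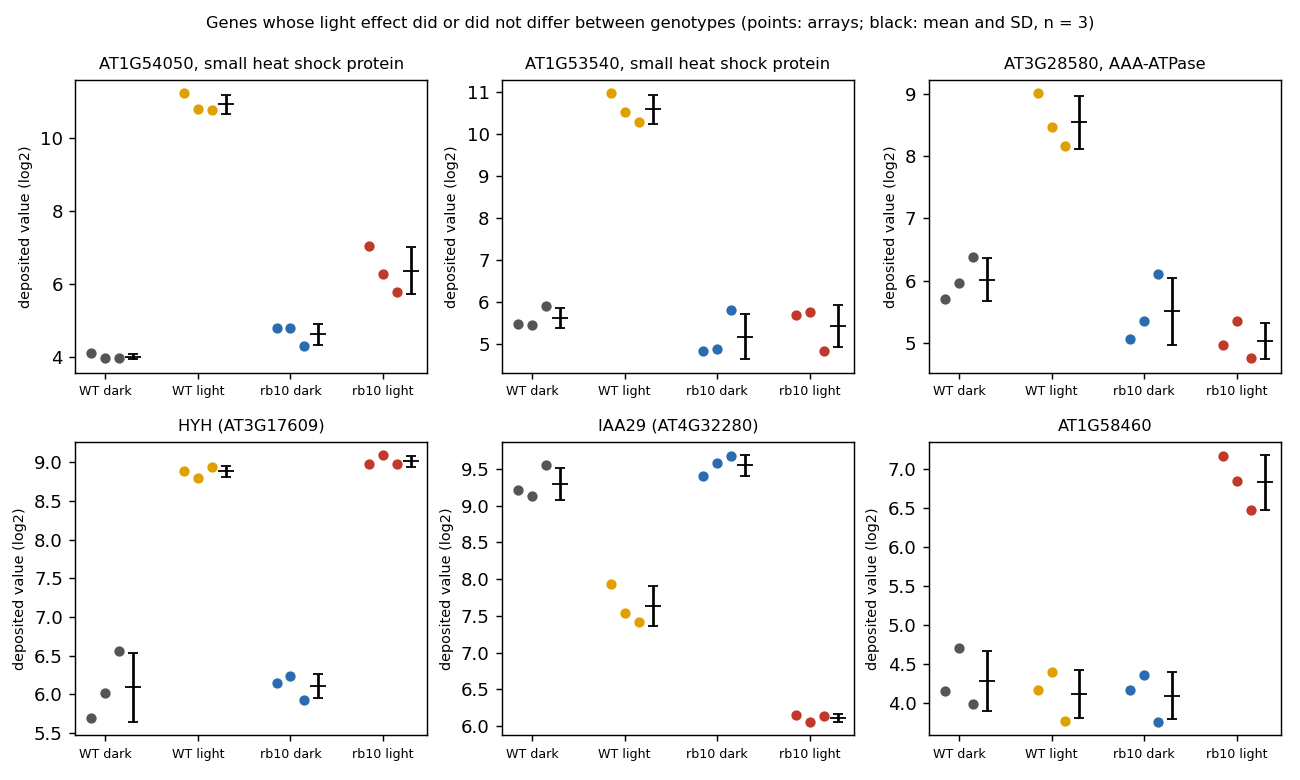
Deposited log2 signal of 6 genes on each array (points) with group mean and SD (black, n = 3), by genotype and light. AT1G54050 and AT1G53540 rise to 10.91 and 10.59 in WT after light and read 6.35 and 5.42 in rb10, while HYH rises in both genotypes.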

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

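The tests of explanations for the array and for the genes induced by light were chosen after the results were seen, as was the count of splits without the array labelled rb10 dark replicate 3. The other counts of splits were planned.

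The light effect differed between the genotypes, by the test of that difference itself, for 380 probe sets. Among the genes named for this difference, it was -5.18 for AT1G54050, -4.84 for AT1G52560, -4.79 for AT2G32200, -4.72 for AT1G53540, -4.00 for ATHSP22.0, -3.00 for AT3G28580 and -1.83 for STZ. It was -1.77 for IAA29, -0.93 for MCCB, -0.83 for PPDK, 0.64 for GI and 1.37 for SPCH. It was 2.16 for AT3G44020, 2.18 for AT4G17670, 2.21 for AT4G29930, 2.40 for AT4G17680 and 2.91 for AT1G58460. Of the genes named for other comparisons, it also passed for AT1G59860 (-3.41), AT1G07400 (-3.26), AT5G05965 (-3.19) and AT3G59130 (1.16).

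Probe sets paired with no gene carried signal that no comparison above uses. Called among these 20927 were 1209 for light in WT, 1154 for light in rb10, 3289 for genotype after light and 303 for the interaction, in a fit of every probe set.

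The array labelled rb10 dark replicate 3 read like WT, at 0.02 on the genotype axis. A mislabelled sample is a candidate explanation. On an axis of 2543 probe sets with no gene, which had not raised the doubt and were chosen from the light arrays alone, it lay at 0.029, the WT dark arrays at -0.027 to 0.022 and the other arrays labelled rb10 dark at 0.463 and 0.483. These values come from the same RNA on the same array. They extend the WT-like reading to more probe sets, and are no independent test of a mislabelled sample. Against a swap with one of the other arrays, no array labelled WT lay above 0.031 on its axis, and against a mixture of rb10 and WT RNA, the position was 3.88 percent of that of the other two arrays labelled rb10 dark. Noise on that array is no better an account, since its values varied around the WT dark mean with an SD of 0.293, against 0.331 for the WT dark arrays around each other. Some genes went the other way. Of 526 genes that differed the same way in both light states, at least 2-fold in the dark, 501 lay nearer WT and 25 nearer rb10. Among the 25 was AT3G59130 (6.74, against 5.53 to 5.65 in WT dark), the only gene called in the dark with every array. How many of the 526 a WT dark array would place nearer rb10 was not computed, so the 25 decide nothing. What the sample was stays open. A swap with a sample outside this series was not tested, and the design gives no biological explanation for 1 array of a group.

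Among the genes that light induced in WT, 217 had a negative interaction, with a median of -1.46 (-1.45 without the array labelled rb10 dark replicate 3), a sign that follows from their choice. Less light reaching the rb10 seedlings, as the whole cause of the interaction, is argued against by 32.6 percent of its calls (124 of 380). With every array under its label, they had a called light effect in rb10 larger in size than in WT. That share was not computed without the array labelled rb10 dark replicate 3. Without it, 79 of 291 negative calls were called down by light in rb10. Of 103 positive calls, 60 were called up there, and less light alone would give neither. A part of less light in these 217 genes stays open. A higher dark level in rb10 is argued against by the median dark difference of 0.07 in these genes, 0.046 of the size of the interaction. Warmer exposure of the WT seedlings cannot be told apart from a genotype difference, since no temperature is recorded and the small heat shock genes, with a median interaction of -3.41, would move in either case. An effect of the rb10 genotype on these light responses may be one explanation, untested here.

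Each count was set against other splits of the same arrays. For light in WT 1 of 10 splits, the real one with 1204 calls, gave as many, and the highest other gave 0. For light in rb10 it was 1 of 10 (1254, highest other 0), for genotype after light 1 of 10 (3355, highest other 0), and for genotype in the dark 2 of 10 (1, highest other 1). Without the array labelled rb10 dark replicate 3 the dark comparison gave 1 of 10 (1761, highest other 23). With 10 splits no share under 0.05 can be reached.

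For the interaction, 7 of 100 regroupings of genotype within each light state gave at least 380 calls, the real one included, and the highest other gave 3564, so that chance is not excluded by this count. All 6 others kept the genotypes after light as labelled and mixed the dark arrays, so they measure a structure of the samples, the large genotype difference after light.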

How the results depend on the processing

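The alternatives, among them leaving out each array in turn, were fixed before the data were examined. Chosen afterwards were the separate repeats of lists, relations and splits without the array labelled rb10 dark replicate 3 as a doubted array. No result reversed its direction while called. Testing every probe set, with more tested, gave 2289 calls for light in WT, 2210 for light in rb10, 0 for genotype in the dark, 6251 for genotype after light and 597 for the interaction. Requiring a fold of 2 as well left 555, 484 and 1197 for light in WT, light in rb10 and genotype after light. The ordinary equal-variance test gave 704, 137 and 0 for light in WT, light in rb10 and genotype in the dark. A fit of the groups of the comparison alone gave 580 for light in rb10 and 0 for genotype in the dark. Both had fewer degrees of freedom, but the latter fit gave 1107 for light in WT and 3442 for genotype after light. Fewer degrees of freedom alone therefore do not account for the 580. The fit of the rb10 groups alone holds the array labelled rb10 dark replicate 3, while those that gave 1107 and 3442 do not. In the fit of all groups that array widened the shared spread (median SE for light in WT 0.174 with it, 0.161 without). The rb10 groups alone were not fitted without it. Genotype in the dark also gave 0 with a trended and robust prior and with a replicate block. The block counts for the others were 1098, 1137, 3181 and 306. Arrays that share a number across groups had r from -0.043 to 0.073, and others from -0.06 to 0.054. These small values show no clear pairing of the samples by number, and do not exclude one. Across genes, the light effects related with r = 0.49 without the dimmest 25% of probe sets. Of 65 list tests 13 passed, 2 with an estimated correlation and 8 after quantile normalization. Where no reason is given, the cause was not tested.

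Leaving out each array in turn gave 839 to 1534 calls for light in WT, 782 to 1154 for light in rb10, 0 to 1761 for genotype in the dark, 2141 to 4120 for genotype after light and 208 to 394 for the interaction, 9 to 13 list calls, and relations of 0.416 to 0.459 and of -0.041 to 0.158. The lowest and highest relation of genotype and light effects came without rb10 dark replicates 3 and 1. The naming rule was applied with and without the array labelled rb10 dark replicate 3, and its genes called with every array were followed. Of these, 16 of 23 (light in WT), 8 of 29 (light in rb10) and 0 of 1 (genotype in the dark) passed in every alternative. It was 27 of 37 for genotype after light and 13 of 18 for the interaction. Other genes mentioned in the text were not counted. AT3G59130 in the dark gave adjusted p = 0.239 with the replicate block. Background levels were not analysed here, so what signal over background limits was not tested.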

Other observations

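The lists, the family test and the test of root share were chosen after the data were seen. Small heat shock and late embryogenesis genes had already been seen among the largest changes. The p-values of those lists are therefore descriptive and not an independent test. Small heat shock proteins, chaperones that hold unfolded proteins, rose with light. All 11 measured members rose in WT after light (median 4.63, camera adjusted p = 2.84e-30, and adjusted p = 0.00128 with an estimated correlation), and 8 rose in rb10 (median 1.71), or 7 without the array labelled rb10 dark replicate 3. The interaction was negative for 8, among them AT1G54050 (-5.18, SE 0.39) and AT5G51440 (-1.76, SE 0.21), and positive for AT4G21870 (1.08, SE 0.21), with a list median of -3.41 (adjusted p = 7.29e-17, and adjusted p = 0.00888 with an estimated correlation). Of 10 measured U-box ubiquitin ligase (PUB) genes, 1 of 36 families of gene symbols tested, 6 rose in WT after light (median 0.82, adjusted p = 1.13e-08, and adjusted p = 0.00628 with an estimated correlation), among them PUB23 (2.75) and PUB19 (1.78). In rb10 2 rose and 1 fell, and the family did not pass (adjusted p = 0.269). After light 6 were lower in rb10 (median -0.70, adjusted p = 0.000815, but adjusted p = 0.0796 with an estimated correlation), and the interaction was negative for PUB54 (-2.27) and PUB23 (-2.04, family adjusted p = 1.04e-05, and adjusted p = 0.0245 with an estimated correlation). With an estimated correlation PUB was the 1 family called for light in WT and for the interaction, and 0 families were called in the other comparisons.

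Of 19 late embryogenesis abundant protein genes, which act in dry seeds and under water loss, 8 were lower in rb10 after light (median -1.26, adjusted p = 2.62e-05, but adjusted p = 0.149 with an estimated correlation), M10 (-1.84, SE 0.29) and AT2G42560 (-1.72, SE 0.41) among them. It was 13 without the array labelled rb10 dark replicate 3 (adjusted p = 2.22e-08, and adjusted p = 0.0384 with an estimated correlation). In the dark 0 of 19 were called with every array, and 0 adjusted over the list alone (limma, median -1.02, adjusted p = 7.19e-05, but adjusted p = 0.31 with an estimated correlation). With the array labelled rb10 dark replicate 3 left out, 12 were lower (median -1.45, adjusted p = 2.22e-10, and adjusted p = 0.0236 with an estimated correlation).

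Genes of 4 esterases that act on suberin, a root barrier polymer, were higher in rb10 after light: AT2G23540 (4.11, SE 0.85), AT1G74460 (3.28, SE 0.57), AT5G37690 (3.07, SE 0.58) and AT3G50400 (3.01, SE 0.59). Their median was 3.18, and no test of this list is given, since the genes were chosen after they were seen to be high. The difference was not confined to light. In the dark 0 were called with every array (median 1.78), and all 4 were called higher without the array labelled rb10 dark replicate 3 (median 2.67, 2.29 to 4.14). The interaction was called for 0 of them in that fit (median 0.47). A larger share of root tissue in the rb10 pools could raise such genes and stays open. The 4 measured root hair genes differed by a median of 0.55 (0.37 to 1.22, 1 called, AT1G30870), which decides nothing, for the same reason.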
